A study of Homo sapiens with 12 samples.

How the data were processed

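RNA of 12 samples was profiled on the Affymetrix PrimeView array, a 3' expression array on which each gene is read by 1 or more sets of short probes. The samples formed 4 groups of 3, Kelly or BE(2)-C cells with DMSO or 1 µM JQ1 for 24 h, as the titles of the samples state. Per the submitters' processing notes the authors used RMA, a method that corrects background, normalizes between arrays and summarises probes into probe sets; its version is not given in the sources used here. RMA values are usually given as log2, but the deposited values are intensity on a linear scale, with array medians of 61.4 to 67.3 and maxima of 32400 to 34820. The tests had been planned for log2 values as deposited, so log2 was taken of each intensity here, with no offset, since no value was at or below 0. No filter, further normalization or floor was applied to the values. Nearly equal medians leave it open what part of any change in total RNA between groups the normalization has removed.

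The table held 49395 probe sets. Of these 102 were controls, 44994 named 1 gene in the platform annotation, 1832 named several and 2473 named none; probe sets naming several or none named no gene here. Symbols were updated through gene identifiers to the GRCh38.p14 gene table, which matched 99.9% of the probe sets naming 1 gene; no coordinates were used, because the array files name no genome build. A gene was read from the probe set with the highest mean over the 12 arrays, which gave 18132 genes, 11735 of them with more than 1 probe set. Probe sets of the same gene passed the threshold in opposite directions in 2 genes in Kelly and 1 in BE(2)-C.

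Each gene was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes without a trend) as the means of the 4 groups over all 12 arrays, so that the groups shared 1 estimate of the spread. The contrasts were JQ1 against DMSO in each line, their average, their difference (BE(2)-C minus Kelly) and BE(2)-C against Kelly under DMSO. P-values were two-sided and adjusted by Benjamini-Hochberg over all genes of a contrast, with a threshold of 0.05; a count at 2-fold adds a limit of 1 on the absolute log2 fold change. The JQ1 effects of the lines share no arrays.

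A total of 24 gene lists with 640 symbols, of which 587 were measured, was written before the data were examined. They cover MYC targets, ribosome biogenesis, ribosomal proteins, DNA replication, mitosis, CDK inhibitors and p53 targets, adrenergic transcription factors, catecholamine genes, neuronal differentiation, mesenchymal genes, BET proteins, histones, the BCL2 family, cholesterol synthesis, the ATF4 response, lysosome, glycolysis, nucleotide synthesis, interferon, immediate-early genes, the neighbours of MYCN, and haematopoietic, epithelial and Schwann cell or fibroblast markers. Lists were tested with limma's camera with a preset correlation of 0.01 between genes, with camera and an estimated correlation, and with fry, each adjusted over the lists. Counts adjusted over the list alone use the members as the only tests.

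The named genes were set by a rule fixed at the same time: 7 genes tied to BET inhibition, 1 of which is not reported here, the 8 highest and 8 lowest passing genes within each line whose groups did not overlap, the 8 and 8 with these properties in both lines, the 8 and 8 of the difference, 6 and 6 between the lines, and up to 4 passing members of each list or the 2 largest where none passed. XIST, Y-linked genes and, outside the lists, symbols of uncharacterised loci were left out. Which of the named list members stand as examples in the text was decided after the values were seen, and members whose call was lost when 1 array was left out were mostly passed over there.

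The replicate numbers of the labels pair DMSO and JQ1 samples by the rule used here only in Kelly, where the residuals of same-numbered samples correlated at 0.434, 0.228 and 0.515; with the hybridization control signal in the model these were 0.283, -0.0881 and -0.0173. These correlations are across genes, which are not independent replicates. The design was kept without a block. The hybridization control signal of an array is the mean log2 intensity of 9 probe sets for the added bacterial transcripts BioB, BioC, BioDn and CreX. The first axis of the variation within groups held 64.1% of it. The slope of the control signal passed the threshold in 9691 genes.

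The gene test was tested on simulated data for the Kelly comparison with all 18132 genes, the spread of these arrays including the shared axis, and 200 changed genes in each of 20 simulations. It recovered 5.1% of changes of 1.41-fold, 50.6% of 2-fold, 93.3% of 4-fold and 99.6% of 8-fold, and 4.39% of its calls were false over all simulations. The false calls of a simulation had a median of 1.5 and a maximum of 25. The simulated shared axis was independent of treatment. In the real arrays that axis followed the control signal (r = 0.961), which was higher with JQ1 in all 3 Kelly pairs. The share of false calls may therefore differ in the real Kelly comparison. For the BE(2)-C comparison with the same genes, a list lowered by 0.5 on the log2 scale was called in 20 of 20 simulations with the preset correlation and in 17 with an estimated one, and 5.35 of 23 unchanged lists were called falsely on average with the preset correlation, and 0 with the estimated one.

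Alternatives were the mean of all probe sets, probe sets without the suffix for cross-hybridizing probes (_x_at), only genes above the median level, quantile normalization, median centring, a trend and robust prior, the replicate block (cell line by replicate number), leaving out each array, and the arrays of 1 line alone. After the data were seen, the control signal as a covariate, its use with the block or with an estimated correlation, and leaving out the 3 arrays of highest control signal were added. Figures were drawn with matplotlib 3.10.9.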

Results

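Gene expression was measured in 2 human neuroblastoma cell lines, Kelly and BE(2)-C, which both carry extra copies of the oncogene MYCN. The cells had been treated for 24 h with 1 µM JQ1 or with DMSO, the solvent that serves as the vehicle control. JQ1 is a small molecule that occupies the acetyl-lysine pocket of the BET bromodomain proteins, BRD2 and BRD3 among them, which bind acetylated chromatin and promote transcription. Each of the 4 groups held 3 Affymetrix PrimeView arrays, 12 in all, and 18132 genes were tested. The number of arrays limits the precision: the median standard error (SE) of a log2 fold change within a line was 0.21. The labels describe treatment in triplicate without saying whether the replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical.

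Arrays of the same group correlated at r = 0.952 to 0.996 over all probe sets, and arrays of different lines at 0.880 to 0.956. The signal of the hybridization controls, bacterial transcripts added in a fixed amount to each labelled sample, varied between arrays from 9.94 to 13.65 on the log2 scale. It averaged 11.90 ± 1.29 (SD, n = 3) in Kelly with DMSO, 12.94 ± 0.69 in Kelly with JQ1, 11.20 ± 1.54 in BE(2)-C with DMSO and 11.41 ± 1.20 in BE(2)-C with JQ1. The JQ1 arrays were higher by 1.04 in Kelly (two-sided exact permutation p = 0.3) and by 0.21 in BE(2)-C (exact p = 0.8), where 3 arrays against 3 cannot give a p below 0.1. Within the same-numbered Kelly pairs it was higher with JQ1 in 3 of 3, by 0.53, 2.19 and 0.39 (exact p over the signs of the pairs = 0.25, the lowest possible), and in 1 of 3 in BE(2)-C. In a fit with this control signal as a covariate, its slope passed the threshold in 9691 of the 18132 genes. The log2 signal of ACTB at the 3' end minus that at the 5' end, a sign of RNA quality, averaged 1.67 ± 0.50 (SD, n = 3) in Kelly with DMSO and 1.72 ± 0.50 with JQ1. In BE(2)-C it averaged 0.91 ± 0.31 with DMSO and 0.89 ± 0.08 with JQ1. In Kelly this value and that of GAPDH were higher with JQ1 in all 3 pairs, by means of 0.05 and 0.12, and in BE(2)-C each in 1 of 3.

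**Figure D1:**
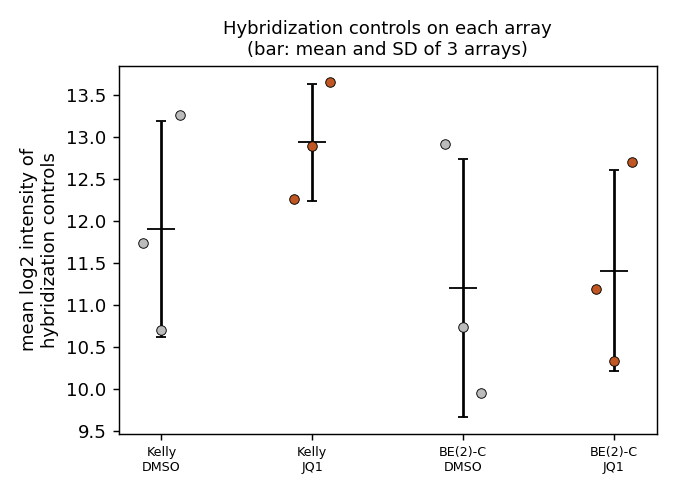
Mean log2 intensity of the 9 hybridization control probe sets on each of the 12 arrays (points), with the mean and SD of the 3 arrays of each group (bars). The arrays span 9.94 to 13.65, and every group holds arrays more than 1 log2 unit apart.

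The first question was whether JQ1 lowered MYCN, the gene named in the title of the series, and whether known response genes of BET inhibition moved. HEXIM1, an inhibitor of the elongation factor P-TEFb that is widely used as a marker of BET inhibition, rose 2.69-fold in Kelly (log2 fold change 1.43, SE 0.17, limma adjusted p = 0.000377) and 4.66-fold in BE(2)-C (2.22, SE 0.17, adjusted p = 2.81e-05). Its other 4 probe sets had log2 fold changes of 1.39 to 2.20 in Kelly and 1.87 to 2.60 in BE(2)-C. SERPINI1, which encodes the protease inhibitor neuroserpin, rose 2.60-fold in Kelly (adjusted p = 0.00305) and 3.03-fold in BE(2)-C (adjusted p = 0.0017). BRD2 rose by 0.83 on the log2 scale averaged over the lines (limma adjusted p = 0.00156). MYCN, read from its brightest probe set, had a log2 fold change of -0.34 in Kelly (from 13.87 ± 0.00721 to 13.53 ± 0.0576, SD, n = 3; adjusted p = 0.136) and of -0.33 in BE(2)-C (from 13.56 ± 0.0668 to 13.24 ± 0.076; adjusted p = 0.209), so neither line passed the threshold of 0.05 with this probe set. Every JQ1 array nevertheless lay below every DMSO array of its line in this probe set. The JQ1 arrays lay at 13.465 to 13.576 against 13.868 to 13.882 with DMSO in Kelly, and at 13.163 to 13.315 against 13.523 to 13.64 in BE(2)-C. With the mean of its probe sets MYCN passed in both, falling by 0.43 in Kelly (limma adjusted p = 0.0333) and by 0.67 in BE(2)-C (adjusted p = 0.00386). It also passed in both with the trend and robust prior (0.0279 and 0.0471). Over all alternatives its adjusted p spanned 0.0279 to 0.891 in Kelly and 0.00386 to 0.563 in BE(2)-C.

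Averaged over the lines, MYCN fell by 0.34 on the log2 scale (SE 0.09, limma adjusted p = 0.0307). That call was lost in a fit with a replicate block (adjusted p = 0.0762). It was also lost without Kelly DMSO replicate 1 (0.0777) or 2 (0.0632), Kelly JQ1 replicate 2 (0.0717), BE(2)-C DMSO replicate 2 (0.0685) or 3 (0.0574) and BE(2)-C JQ1 replicate 1 (0.0608), 2 (0.0899) or 3 (0.0633). Over all alternatives the adjusted p of MYCN in the average spanned 0.000564 to 0.487. The other 3 MYCN probe sets differed in size. The one at a mean level of 13.45 had log2 fold changes of -0.05 in Kelly and -0.32 in BE(2)-C, the one at 12.15 of -0.77 and -1.03, and the one at 7.42 of -0.55 and -0.99. When all probe sets that name 1 gene were tested, the probe sets at 12.15 and 7.42 passed in BE(2)-C (limma adjusted p = 0.0167 and 0.00497) and not in Kelly (0.0525 and 0.0709). BRD3, read from its brightest probe set, had log2 fold changes of 0.45 and 0.50 that passed in the average (0.48, SE 0.12, adjusted p = 0.0203) and in neither line. Its probe set at a mean level of 10.45 had log2 fold changes of 0.55 and 0.50. When all probe sets were tested, that one passed in Kelly (limma adjusted p = 0.0255) and not in BE(2)-C (0.0536). The BRD3 call was lost without Kelly JQ1 replicate 1 (0.0517) or 2 (0.0558) and without BE(2)-C JQ1 replicate 3 (0.0516), within a range of 0.00134 to 0.124 over the alternatives for BRD3. MYC was dim, near 4.1, and had log2 fold changes of -0.07 and 0.15 (adjusted p = 0.794 and 0.879).

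**Figure D2:**
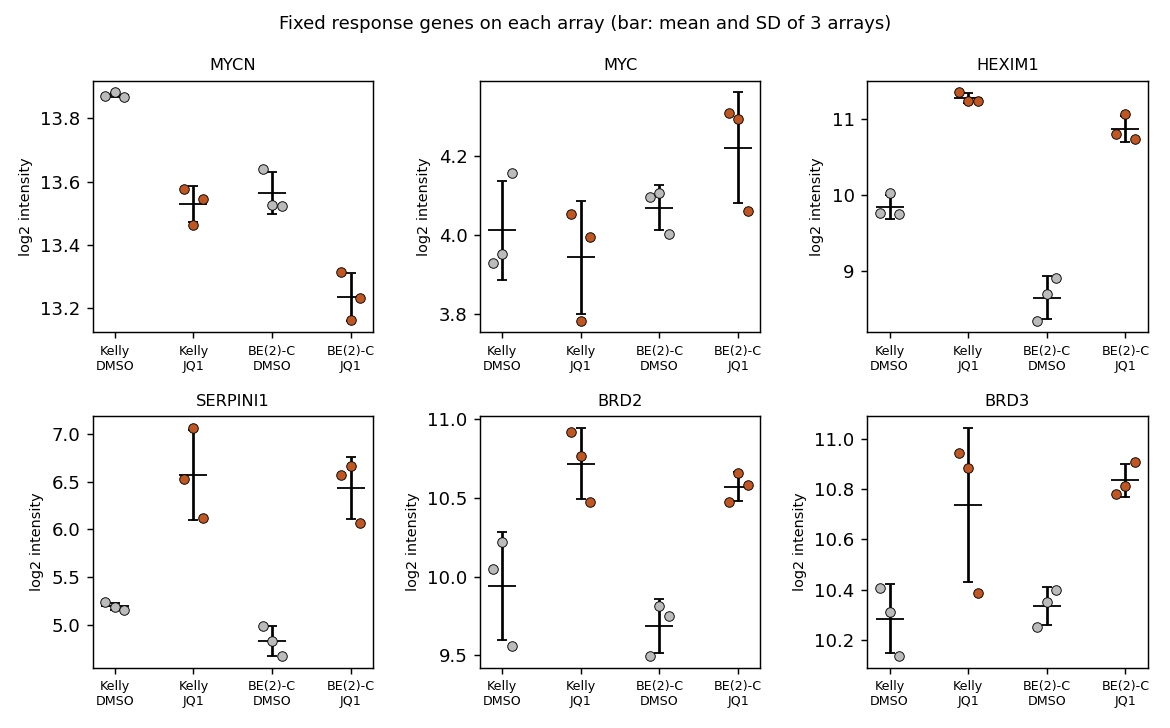
Log2 intensity of MYCN, MYC, HEXIM1, SERPINI1, BRD2 and BRD3 on each array (points), with the mean and SD of the 3 arrays of a group (bars); each panel has its own vertical axis. HEXIM1 moved from 9.85 to 11.28 in Kelly and from 8.65 to 10.87 in BE(2)-C, while MYCN lay between 13.24 and 13.87 in all group means.

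The next question was which genes JQ1 changed in each line. In Kelly cells, IGFBP5, a secreted binding protein of insulin-like growth factors, fell by 4.56 on the log2 scale (SE 0.17, limma adjusted p = 4.18e-08) in its brightest probe set, while its other 5 probe sets had log2 fold changes between -2.21 and 0.65. OPRL1, the nociceptin receptor, fell by 3.73, and P2RX5, an ATP-gated channel (-3.51), HOXC8, a homeobox transcription factor (-3.46), and SST, which encodes somatostatin (-3.43), also fell. COL6A6, a collagen chain (-3.34), HDAC9, a histone deacetylase (-3.33), and MAOA, which breaks down monoamines (-3.33), followed. The largest rises by the rule for named genes were SCARNA20, a small Cajal body RNA (2.63, SE 0.40, adjusted p = 0.0017), and the histone gene H2BC5 (2.45, SE 0.15, adjusted p = 2.04e-06), followed by MIR7-3HG (2.19), H2AC11 (2.00), the histone pseudogene H2BC20P (1.93), PLCL1 (1.91), FILIP1L (1.88) and H2AC7 (1.85). With the mean of a gene's probe sets the changes of several were smaller and still passed: -1.51 for IGFBP5, -1.67 for OPRL1, -1.03 for HDAC9, 1.13 for PLCL1 and 0.42 for FILIP1L.

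Altogether 1178 genes passed in Kelly, 320 higher and 858 lower, and 114 and 551 of these changed at least 2-fold. Falls made up 72.8% of the calls; with quantile normalization the split was 608 higher and 862 lower, a share of 58.6%. By the rule that named them, the genes with these largest changes had all 3 JQ1 arrays beyond the 3 DMSO arrays, which chance gives in 10% of genes. The count was 603 without DMSO replicate 1, 680 without DMSO replicate 2, 750 without JQ1 replicate 2, 2167 without DMSO replicate 3, and 584 with the 6 Kelly arrays alone, and the count at 2-fold was 1192 without DMSO replicate 3. The full count was 2293 with the control signal as a covariate, 881 higher and 1412 lower (61.6% lower), and all 1178 genes were among them. Without the 3 arrays of highest control signal it was 4502, 2196 higher and 2306 lower (51.2% lower). Both of these alternatives were added after the data were seen. The control signal was higher with JQ1 in all 3 Kelly pairs. The 3 arrays left out were Kelly JQ1 replicate 3, Kelly DMSO replicate 3 and BE(2)-C DMSO replicate 1. The remaining Kelly arrays lay at 12.27 and 12.89 with JQ1 and at 11.74 and 10.70 with DMSO. Leaving arrays out thus did not even the control signal, and its counts cannot show whether that signal shaped the calls.

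Of 17 measured catecholamine and dense-core vesicle genes 7 fell in Kelly, 3 rose and 7 did not pass. MAOA (-3.33), the vesicular transporter SLC18A1 (-2.11), the rate-limiting enzyme of dopamine synthesis TH (-1.90) and the decarboxylase DDC (-1.68) were among those that fell. GCH1 (1.53), which makes a cofactor of TH, the granin SCG2 (1.65) and VGF (0.93) rose, and were named after their values were seen. Adjusted over the list alone, 8 fell and 5 rose. Among 21 adrenergic transcription factors 5 fell, including LMO3 (-1.91), KLF7 (-1.65) and LMO1 (-1.55), and SOX11 rose (1.26; also named after its value was seen). Of 51 MYC target genes 7 fell and 0 rose, including MYBBP1A (-1.07), which acts on ribosomal RNA genes, and 12 fell adjusted over the list alone. Among 19 histone genes 9 rose and 0 fell (12 rose adjusted over the list alone), including H2AC6 (1.63) and H2AC8 (1.62). With the mean of their probe sets DDC fell by 0.62, LMO3 by 1.09 and MYBBP1A by 0.61.

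In Kelly, limma's camera test with a preset correlation of 0.01 called 8 lists. The histone genes were higher (median log2 fold change 0.97, camera adjusted p = 4.46e-08; adjusted p = 0.519 with an estimated correlation). The lists that were lower were MYC target genes (median -0.35, adjusted p = 6.13e-07; adjusted p = 0.583 with an estimated correlation), ribosome biogenesis (-0.33, adjusted p = 2.79e-06; adjusted p = 0.519 with an estimated correlation), mitosis (-0.28, adjusted p = 5.5e-05; adjusted p = 0.584 with an estimated correlation), nucleotide and polyamine synthesis (-0.47, adjusted p = 0.000427; adjusted p = 0.583 with an estimated correlation) and ATF4 and unfolded protein response (-0.33, adjusted p = 0.00522; adjusted p = 0.583 with an estimated correlation). The catecholamine list (-0.84, adjusted p = 0.0216; adjusted p = 0.583 with an estimated correlation) and glycolysis (-0.24, adjusted p = 0.0473; adjusted p = 0.695 with an estimated correlation) were also lower. With the control signal as a covariate the calls of the catecholamine list and glycolysis ended (adjusted p = 0.0546 and 0.376). No list call in Kelly held with an estimated correlation. Of the 8 lists 3 also passed fry, limma's rotation test of movement in one direction: histone genes (fry adjusted p = 0.00699), ribosome biogenesis (0.0339) and the catecholamine list (0.0339). The other 5 did not pass fry (adjusted p from 0.0523 for MYC target genes to 0.22 for glycolysis). Fry called 2 lists that camera did not, BET proteins and P-TEFb regulators and immediate-early genes, for 5 in all. In simulations of the BE(2)-C comparison with the shared variation of these arrays the preset correlation falsely called 5.35 of 23 unchanged lists on average, against 0 with an estimated correlation.

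In BE(2)-C cells, members of the histone list were among the largest rises. H2BC21 rose 11.8-fold (log2 fold change 3.57, SE 0.27, limma adjusted p = 2.81e-05), H2BC8 10.6-fold (3.40), and TP53INP1, a p53-induced gene linked to autophagy and cell death, 10.4-fold (3.38, SE 0.24, adjusted p = 1.93e-05). H2AC8 (3.24), H3C10 (3.23), H2AC6 (2.98), H2AC11 (2.97) and MIR7-3HG (2.92) followed. The largest falls by the rule for named genes were the tubulin TUBA1C by 3.36 (SE 0.23, limma adjusted p = 1.48e-05) and the phosphatase PPEF1 by 3.13. The serotonin receptor HTR2B (-3.11), the tetraspanin TSPAN8 (-3.09), CDKAL1 (-2.60), ARL9 (-2.53), the adenosine receptor ADORA2B (-2.48) and HDAC9 (-2.44) followed. With JQ1, HTR2B lay at 3.84, PPEF1 at 4.32 and TSPAN8 at 4.70. Signal over background was not estimated there, so the sizes and order of these falls are uncertain. With the mean of a gene's probe sets the log2 fold change was 1.18 for H2BC21, 1.71 for TP53INP1, 1.96 for H2AC11, -1.22 for CDKAL1 and -0.71 for HDAC9, all of which still passed.

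Of 850 genes that passed in BE(2)-C, 395 were higher and 455 lower, and 195 and 225 changed at least 2-fold. By the rule that named them, the BE(2)-C genes given above for the largest changes also had all 3 JQ1 arrays beyond the 3 DMSO arrays. The count was 322 without JQ1 replicate 1, 386 without JQ1 replicate 2, 471 without JQ1 replicate 3, 407 without DMSO replicate 2, 539 without DMSO replicate 3, and the count at 2-fold was 265 without JQ1 replicate 1. Falls made up 53.5% of the 850. The count was 2751 with the control signal as a covariate, which included all 850, and rises then outnumbered falls (1485 higher and 1266 lower, 46.0% lower). Without the 3 arrays of highest control signal it was 2565, 1013 higher and 1552 lower (60.5% lower). The control signal of the remaining BE(2)-C arrays lay at 10.74 and 9.94 with DMSO and at 11.19, 10.33 and 12.70 with JQ1. That setting thus made the groups less alike in control signal.

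Of 19 histone genes 13 rose and 0 fell in BE(2)-C, and 15 rose adjusted over the list alone. H2BC5 (2.64) was among them. When all probe sets of these genes were read, the 15 without an _s_at or _x_at suffix had a median of 0.59 in Kelly (5 rose) and 1.24 in BE(2)-C (10 rose). The 24 with such a suffix had medians of 0.40 (5 rose) and 0.78 (12 rose). Probe sets with such a suffix can read more than 1 related gene, so the members may not be separate counts. Of 51 MYC target genes 13 fell and 0 rose (27 fell adjusted over the list alone), led by NOP16 (-1.29), PPRC1 (-1.27) and DCTPP1 (-1.15). Of 40 DNA replication genes 9 fell and 0 rose (20 fell adjusted over the list alone), including GINS1 (-1.12), a subunit of the replicative helicase. Of 34 mitosis genes 5 fell, including the cyclin CCNA2 (-0.72), whose call was lost without JQ1 replicate 2 (limma adjusted p = 0.0872) or 3 (0.0678) or DMSO replicate 3 (0.0559), within a range of 0.00137 to 0.0872 over its alternatives. Among 17 catecholamine genes 5 fell, with SLC18A1 (-2.16), DBH (-1.60) and TH (-1.48) lowest, and 5 rose, including the granins CHGA (0.63) and CHGB (0.79), named after their values were seen, and the neuropeptide precursor VGF (1.28). Of 21 adrenergic transcription factors 2 rose and 1, TFAP2B (-1.08), fell. The immediate-early transcription factor KLF2 rose by 2.16.

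In BE(2)-C, limma's camera test called 11 lists, and 1 of them held with an estimated correlation: the histone genes (median log2 fold change 1.30, adjusted p = 8.0e-26; adjusted p = 0.0312 with an estimated correlation). With the estimated correlation and the control signal as a covariate together that call was lost as well (adjusted p = 0.069), the highest in a range from 4.25e-28 over its alternatives. Lower lists were MYC target genes (median -0.61, adjusted p = 4.61e-20; adjusted p = 0.0844 with an estimated correlation), ribosome biogenesis (-0.46, adjusted p = 1.21e-13; adjusted p = 0.0831 with an estimated correlation), DNA replication (-0.48, adjusted p = 1.21e-13; adjusted p = 0.0844 with an estimated correlation), mitosis (-0.54, adjusted p = 9.0e-10; adjusted p = 0.222 with an estimated correlation), nucleotide and polyamine synthesis (-0.51, adjusted p = 3.89e-07; adjusted p = 0.182 with an estimated correlation) and Schwann cell and fibroblast markers (-0.10, adjusted p = 0.00937; adjusted p = 0.182 with an estimated correlation), where the matrix proteoglycan DCN (-1.88, and -1.06 with the mean of its probe sets) fell. Higher lists were BET proteins and P-TEFb regulators (0.29, adjusted p = 0.00023; adjusted p = 0.0844 with an estimated correlation), lysosome and autophagy (0.23, adjusted p = 0.000428; adjusted p = 0.136 with an estimated correlation), immediate-early genes (0.27, adjusted p = 0.00299; adjusted p = 0.0863 with an estimated correlation) and CDK inhibitors and p53 targets (0.15, adjusted p = 0.0478; adjusted p = 0.315 with an estimated correlation). The same 11 lists passed fry.

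**Figure D3:**
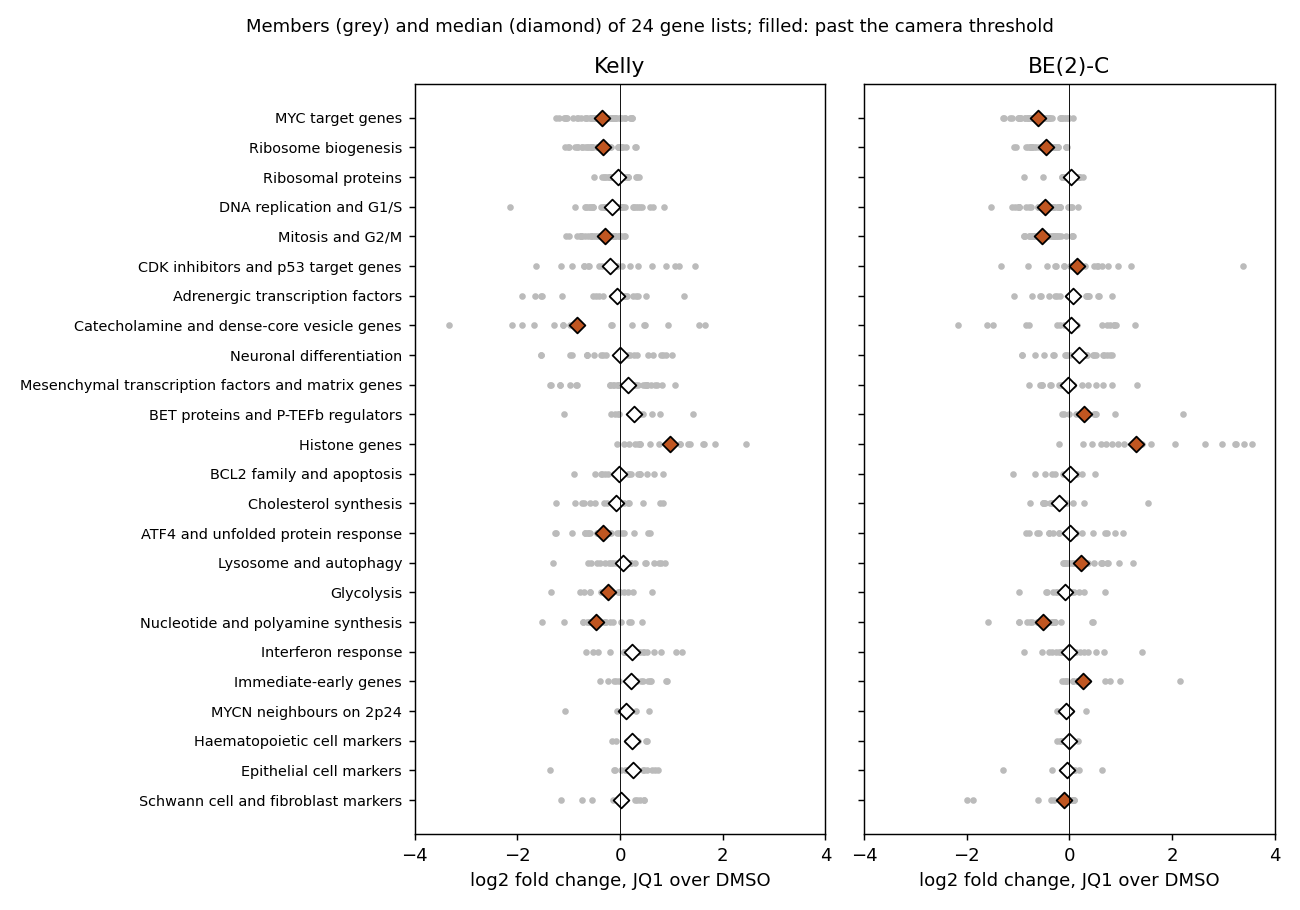
Log2 fold change of JQ1 over DMSO for the measured members (grey points) and the median (diamonds) of 24 gene lists in Kelly (left) and BE(2)-C (right); filled diamonds passed the camera threshold of 0.05 with a preset correlation. With 1 probe set per gene, the histone list had the highest median in both lines, 0.97 and 1.30.

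The response common to the lines was asked through genes that passed in both. Among those whose JQ1 and DMSO arrays did not overlap in either line, the rises were led by MIR7-3HG (average log2 fold change 2.55, SE 0.21, limma adjusted p = 1.73e-05), which hosts a microRNA, H2BC5 (2.54), H2AC11 (2.48), H2BC21 (2.46), SCARNA20 (2.44), H2AC8 (2.43), H2AC6 (2.31) and TP53INP1 (2.23). H2BC8 averaged 2.62 (adjusted p = 0.0003), but its arrays overlapped in Kelly. By the same rule the falls were led by IGFBP5 (-3.18, SE 0.12, adjusted p = 5.01e-08), HDAC9 (-2.89), HOXC8 (-2.81), the paraoxonase PON2 (-2.58), COL6A6 (-2.57), P2RX5 (-2.54), the cAMP phosphodiesterase PDE4B (-2.46) and GTF3C6 (-2.42), a subunit of the RNA polymerase III factor TFIIIC. With the mean of a gene's probe sets the averages were -1.50 for IGFBP5, -0.87 for HDAC9, -0.73 for PDE4B, 0.86 for H2BC21 and 1.14 for TP53INP1, and these still passed.

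In all, 110 genes were higher in both lines and 211 lower in both, where independent lists would give 6.97 and 21.5, while 0 were higher in Kelly and lower in BE(2)-C and 1 the opposite. The tests of both lines use the same estimate of a gene's spread, so a gene with a small spread passes more easily in both. The counts for independent lists may therefore be too low. Across all genes, which are not independent replicates, the log2 fold changes of the lines had a Pearson r of 0.366 and a Spearman rho of 0.203. Of 1706 genes past the threshold in either line, 85.9% had the same sign in both. The average passed in 2005 genes, 729 higher and 1276 lower (63.6% lower); with quantile normalization the split was 1114 and 1287 (53.6% lower). With the control signal as a covariate 3683 genes passed, 1716 higher and 1967 lower (53.4% lower), with 470 higher and 562 lower in both lines. Without the 3 arrays of highest control signal 5815 passed, 2884 higher and 2931 lower (50.4% lower). That setting left the mean control signal higher with JQ1 in both lines. The 110 became 52 without Kelly DMSO replicate 1, 71 and 58 without Kelly JQ1 replicates 1 and 2, 53 and 64 without BE(2)-C JQ1 replicates 1 and 2, and 63 without BE(2)-C DMSO replicate 2. The 211 became 128 without Kelly DMSO replicate 1, 100, 118 and 113 without BE(2)-C JQ1 replicates 1, 2 and 3, and 115 and 124 without BE(2)-C DMSO replicates 2 and 3. The r became 0.578 and 0.191 without BE(2)-C DMSO replicates 1 and 3 and 0.254 without BE(2)-C JQ1 replicate 3.

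**Figure D4:**
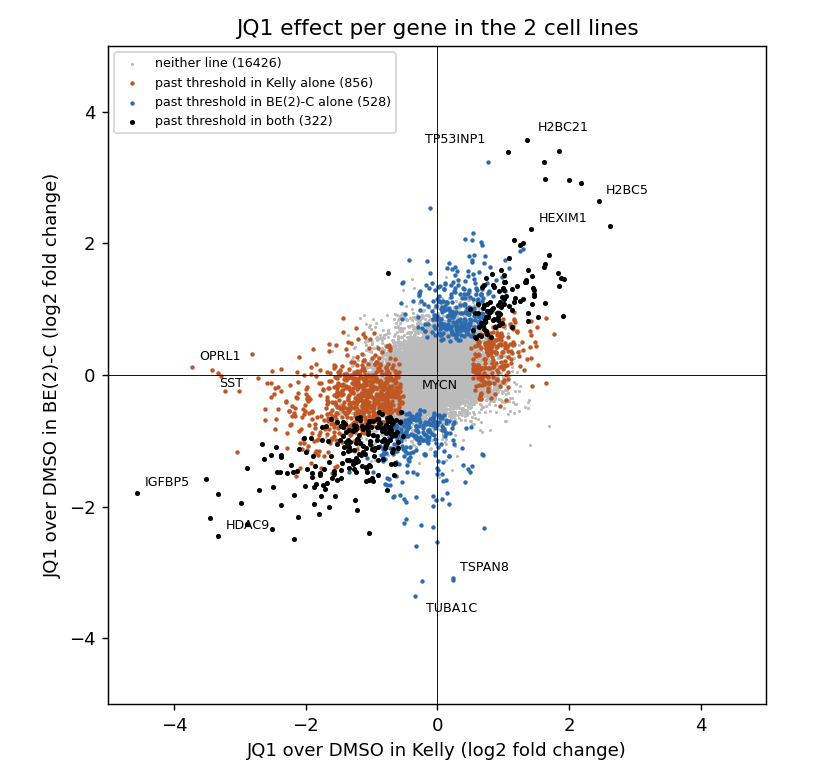
Log2 fold change of JQ1 over DMSO in Kelly (horizontal) and BE(2)-C (vertical) for 18132 genes, coloured by the line in which they passed adjusted p 0.05, with selected genes named. Genes past the threshold in both lines lie in the upper right (110) and lower left (211), with 1 in the upper left.

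Averaged over the lines, camera called 13 lists, 4 higher and 9 lower, of which 10 also passed fry and 0 held with an estimated correlation (lowest adjusted p = 0.093). Of 51 MYC target genes 21 fell and 0 rose (33 fell adjusted over the list alone; median -0.51, limma camera adjusted p = 5.86e-17; adjusted p = 0.162 with an estimated correlation), and of 38 ribosome biogenesis genes 15 fell and 0 rose (-0.37, adjusted p = 7.08e-13; adjusted p = 0.0952 with an estimated correlation). GAR1 (-1.04) and BRIX1 (-0.93), which act in the maturation of ribosomal RNA, were the lowest. Of 58 ribosomal protein genes 1, RPL27A, fell, and the list did not pass (median -0.02, adjusted p = 0.7). Its mean level was 13.58 on the log2 scale, against 9.66 for ribosome biogenesis. A compressed scale of bright probe sets may hide changes at that level, which was not tested for this list. The RPL27A call was lost with the replicate block (0.0528) and without Kelly DMSO replicate 1 (0.095) or 2 (0.0869), Kelly JQ1 replicate 1 (0.0674) or 2 (0.0945), BE(2)-C DMSO replicate 2 (0.0673) or 3 (0.0845) and BE(2)-C JQ1 replicate 1 (0.0934), 2 (0.0629) or 3 (0.0816), within a range of 0.000764 to 0.095. Histone genes rose in 13 of 19 (1.16, adjusted p = 6.62e-18; adjusted p = 0.093 with an estimated correlation). BCL2, an inhibitor of apoptosis, fell by 0.79 and BCL2L11, which promotes it, rose by 0.67, within a list of 20 that did not pass (adjusted p = 0.931). The BCL2L11 call was lost with the mean of its probe sets (adjusted p = 0.137, the highest in a range from 0.000554).

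Of 24 neuronal differentiation genes 5 rose, among them TUBB3 (0.84), and 5 fell, among them GAP43 (-0.95) and DCX (-0.93; -0.53 and -0.42 with the mean of their probe sets), and the list did not pass (limma camera adjusted p = 0.931). Cholesterol synthesis was lower, with 4 of 19 falling and TM7SF2 rising by 1.19 (adjusted p = 0.0404; adjusted p = 0.308 with an estimated correlation). The mesenchymal list (1 rose and 4 fell of 34, adjusted p = 0.95), interferon response (2 and 1 of 26, adjusted p = 0.155), the MYCN neighbours on 2p24 (0 and 0 of 5, adjusted p = 0.95), haematopoietic markers (0 and 0 of 14, adjusted p = 0.466) and epithelial markers (0 and 1 of 15, the keratin KRT19 by -1.33; adjusted p = 0.518) did not pass. In Kelly the interferon list did not pass (adjusted p = 0.0524; adjusted p = 0.695 with an estimated correlation), but did so with the replicate block (higher, adjusted p = 0.0454). Its median of 0.23 in Kelly was not particular to it. Other dim lists there had medians of 0.24 (haematopoietic), 0.25 (epithelial) and 0.02 (Schwann cell and fibroblast markers). The block ended the calls of the average for lysosome genes (adjusted p = 0.0555) and Schwann cell and fibroblast markers (0.0876), and the control signal as a covariate ended those for cholesterol synthesis (0.0658), ATF4 (0.26) and glycolysis (0.313).

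Responses that differed between the lines were tested as an interaction, and 101 genes passed: 80 had a more positive change in BE(2)-C and 21 a more negative one. OPRL1 had log2 fold changes of -3.73 in Kelly and 0.12 in BE(2)-C, a difference of 3.85 (SE 0.29, limma adjusted p = 0.000151). SST (3.50), MAOA (3.36), TNS3 (3.28), the peptide precursor CARTPT (2.99) and IGFBP5 (2.77) also changed more negatively in Kelly. TSPAN8 (-3.33), FGL1 (-3.04), TUBA1C (-3.02), PPEF1 (-2.89), ARL9 (-2.54), RIN2 (-2.24), ENG (-2.13) and MBOAT4 (-2.04) changed more negatively in BE(2)-C. The median level of all genes was 6.68. In BE(2)-C with DMSO, SST lay at 4.09, TNS3 at 4.72, CARTPT at 4.82, MAOA at 5.78, OPRL1 at 6.44 and IGFBP5 at 11.06. In Kelly with DMSO, TSPAN8 lay at 3.85, PPEF1 at 4.00, ARL9 at 4.39, MBOAT4 at 4.77, RIN2 at 5.16 and FGL1 at 6.53. ENG at 7.11 and TUBA1C at 12.64 lay above the median there. The dimmest had little room to fall, so their differences may partly reflect level.

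Within lists, RET, a receptor tyrosine kinase, fell by 1.54 in Kelly and differed by 1.99 between the lines (limma adjusted p = 0.00787). The histone gene H3C10 (2.47) and TP53INP1 (2.31) rose more in BE(2)-C. With the mean of their probe sets the differences were 1.73 for OPRL1, 1.09 for TNS3 and 1.14 for TP53INP1, which still passed. The IGFBP5 difference rests on its brightest probe set: with the mean of all its probe sets the difference was 0.02 (adjusted p = 0.976, the highest over its alternatives, which start at 8.62e-06). The count of 101 became 46, 65 and 212 without Kelly DMSO replicates 1, 2 and 3, 55 without Kelly JQ1 replicate 2, 39, 48 and 48 without BE(2)-C JQ1 replicates 1, 2 and 3, and 58 and 64 without BE(2)-C DMSO replicates 2 and 3. It was 686 with the control signal as a covariate, which included all 101, with 460 more positive in BE(2)-C and 226 more negative. Without the 3 arrays of highest control signal it was 457, with 292 more positive and 165 more negative.

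The lines differed widely after 24 h with DMSO: 1305 genes were higher in BE(2)-C and 1430 in Kelly, 776 and 756 of them by at least 2-fold. In the same arrays the 3' minus 5' signal of ACTB averaged 1.67 in Kelly and 0.91 in BE(2)-C, a difference of -0.75 on the log2 scale (two-sided exact permutation p = 0.2, where 0.1 is the lowest possible). VIP, which encodes vasoactive intestinal peptide, was higher in BE(2)-C by 6.91 on the log2 scale (SE 0.24, limma adjusted p = 1.33e-09), followed by B3GALNT1 (6.55), IL13RA2 (5.94), EDIL3 (5.87), RELN (5.86) and S100A6 (5.77). The adhesion protein CNTNAP2 was higher in Kelly (log2 -6.72 for BE(2)-C over Kelly, SE 0.19, adjusted p = 3.14e-10), followed by EPB41L3, GTSF1, STK26, BMP7 and PLOD2. In the line with less signal these 12 genes lay between 3.82 (EDIL3) and 5.99 (S100A6), with VIP at 4.99 and CNTNAP2 at 4.96. Signal over background was not estimated there, so the sizes and their order are uncertain. With the mean of their probe sets EDIL3 differed by 2.12, EPB41L3 by -3.78 and STK26 by -3.80. Among the lists, 9 of 34 mitosis genes were higher in BE(2)-C and 0 lower (adjusted p = 0.00677; adjusted p = 0.885 with an estimated correlation), and 8 of 21 adrenergic transcription factors (adjusted p = 0.00928; adjusted p = 0.535 with an estimated correlation) and 9 of 21 CDK inhibitor and p53 target genes (adjusted p = 0.000228; adjusted p = 0.471 with an estimated correlation) were higher in Kelly, against 1 in BE(2)-C in each. Of 17 catecholamine genes 7 were higher in BE(2)-C and 3 in Kelly, and the member with the largest difference, MAOA (-5.87), was higher in Kelly; the list was called higher in BE(2)-C (adjusted p = 0.0223; adjusted p = 0.535 with an estimated correlation). So were the Schwann cell and fibroblast markers, with 5 of 13 higher there and 1 lower (adjusted p = 0.0195; adjusted p = 0.487 with an estimated correlation). The covariate of control signal gave 4798 genes, and the calls for mitosis (0.142) and the catecholamine list (0.121) ended. Camera called 5 lists, of which 4 also passed fry, and 3 without BE(2)-C DMSO replicate 3.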

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

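The tests of array signal strength, of normalization and of the level in the line with the smaller change, and the dimmer control genes in the test of bright probe sets, were chosen after the results were seen, as were the splits refitted with a covariate. The test of bright probe sets itself and the counts of splits were set beforehand.

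Genes stood out because their change differed between the lines in the interaction test. The differences (BE(2)-C minus Kelly, log2) were 3.85 for OPRL1, 3.50 for SST, 3.36 for MAOA, 3.28 for TNS3, 3.14 for ANXA2P2, 2.99 for CARTPT, 2.77 for MTUS1, 2.77 for IGFBP5 and 1.93 for P2RX5, all of which fell in Kelly. They were 2.47 for H3C10, 2.21 for H2BC21 and 2.31 for TP53INP1, which rose in BE(2)-C. Among members of the fixed lists they were 2.02 for KLF7, 1.99 for RET, 1.94 for IRF9, 1.63 for KLF2 and -1.95 for DCN. Negative differences were found for TSPAN8 (-3.33), FGL1 (-3.04), TUBA1C (-3.02), PPEF1 (-2.89), ARL9 (-2.54), RIN2 (-2.24), ENG (-2.13) and MBOAT4 (-2.04). Leaving out 1 array ended some of these calls. ANXA2P2 lost its call without Kelly DMSO replicate 1 (limma adjusted p = 0.0641), Kelly JQ1 replicate 2 (0.0595) or 3 (0.0549) and BE(2)-C JQ1 replicate 1 (0.0647), 2 (0.0626) or 3 (0.0555), in a range of 0.000181 to 0.0647 over its alternatives. MTUS1 lost it without Kelly DMSO replicate 1 (0.107) or 2 (0.0641), Kelly JQ1 replicate 2 (0.0981) or 3 (0.0854), BE(2)-C DMSO replicate 2 (0.0583) or 3 (0.0552) and BE(2)-C JQ1 replicate 1 (0.109), 2 (0.112) or 3 (0.0594), and at 1.73 with the mean of its probe sets (0.13), in a range from 0.000225. KLF7 lost it without Kelly DMSO replicate 1 (0.0724), Kelly JQ1 replicate 2 (0.0584) and BE(2)-C JQ1 replicate 1 (0.0683), 2 (0.0662) or 3 (0.0594), and with the mean of its probe sets (0.195), in a range from 0.000762. H2BC21 lost it without Kelly DMSO replicate 1 (0.0757) or 2 (0.0634), Kelly JQ1 replicate 2 (0.081) or 3 (0.0617) and BE(2)-C JQ1 replicate 1 (0.0833) or 2 (0.0705), and with the mean of its probe sets (0.124), in a range from 0.000346. KLF2 lost it without Kelly DMSO replicate 1 (0.0741) and BE(2)-C JQ1 replicate 1 (0.0732), 2 (0.0581) or 3 (0.0594) and with the replicate block (0.0524), in a range from 0.00324. IRF9 lost it without any 1 array but Kelly DMSO replicate 3 (0.0591 to 0.166), with quantile normalization, median centring and the replicate block (0.0892), and with the mean of its probe sets (0.193), in a range from 0.00346. IGFBP5 had a difference of 0.02 with the mean of its probe sets (0.976), in a range from 8.62e-06.

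Of the 24 lists, 8 differed between the lines by limma's camera with the preset correlation, and none of these calls held with an estimated correlation (lowest adjusted p = 0.532) or in fry. More positive in BE(2)-C were histone genes (adjusted p = 4.97e-06), CDK inhibitors and p53 targets (0.00678), catecholamine genes (0.00678), adrenergic transcription factors (0.023), the ATF4 response (0.0257) and lysosome genes (0.0416). More negative there were DNA replication (5.03e-05) and MYC target genes (0.0189). With the control signal as a covariate the adrenergic (0.153) and ATF4 (0.0509) calls ended, and with the replicate block the interferon list differed (0.0453).

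A first explanation for responses that differ is a gene too dim in 1 line to fall there, which bears on the 82 of the 101 genes whose larger change was a fall. Of these, 56.1% lay under the median level of all genes in the line with the smaller change (95% exact interval 44.7% to 67%), against 22.6% of 1019 falling genes without a called difference. That is consistent with low expression for part of them. It is argued against for another part, since in 24 of the 82 the line with the smaller change had a DMSO level at or above that of the other line. TUBA1C was at 12.64 in Kelly, where it did not pass, and at 9.39 in BE(2)-C. Among the 24, IGFBP5 had a difference of 0.02 with the mean of its probe sets. ANXA2P2, MTUS1 and KLF7, also among them, lost their calls in some alternatives. A biological difference between the lines stays open for the 24 and for the 19 genes whose larger change was a rise, and was not tested. Whether a compressed scale at higher levels made changes smaller in the brighter line was not tested either.

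Falls outnumbered rises in Kelly, 858 against 320 (72.8% of calls). With the control signal as a covariate the share was 61.6%, and 52.3% to 65.6% when 1 Kelly array was also left out (lowest without JQ1 replicate 3), with quantile normalization it was 58.6%, and 51.7% to 64.9% (lowest without DMSO replicate 3), and without the 3 arrays of highest control signal it was 51.2%. The covariate kept all 858 falls and 320 rises and added 554 and 561, quantile normalization kept 729 and 306 and added 133 and 302, and leaving out the 3 arrays kept 848 and 316 and added 1458 and 1880. Falls of at least 2-fold went from 551 to 489, 489 and 814 and such rises from 114 to 139, 196 and 291, so the lower shares came with added rises in each of these 3 settings, and also with falls lost in quantile normalization and fewer 2-fold falls with the covariate. Leaving out the 3 arrays left the control signal higher with JQ1 in Kelly, so that setting cannot decide on array signal strength. Whether array signal strength or the authors' normalization added falls or hid rises stays open, and a response of the cells was not tested apart from them.

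The brightest MYCN probe sets fell least. In 6 other genes with a probe set above 13 and a dimmer one that passed in the average, the bright one showed a median of 0.204 of the dimmer one's change (95% bootstrap interval 0.0587 to 0.433), and in MYCN 0.312. In 87 genes whose brighter probe set was at an intermediate level the median ratio was 0.636 (0.566 to 0.757). A ratio under 1 thus arose without a probe set above 13. Choosing a passing probe set may cause it, but this was not separated from other differences between probe sets. A compressed scale of bright probe sets may therefore be part of the small MYCN change, as a hypothesis from few genes; probe sets that read different transcripts were not tested.

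How often other splits of the same arrays give as many genes was counted. In the average, 2 of 100 splits within the lines gave as many genes, the real one with 2005 and another with 2715. That other split had the largest contrast in hybridization control signal of the 100 (-1.82 on the log2 scale), while the splits with the next 3 largest (1.46, -1.43 and 1.35) gave 0 genes. With the control signal as a covariate the split with 2715 gave 0 genes, the real one 3683 and the highest of the rest 1238. For the difference, each gene's average effect of JQ1 over the lines was first taken out of the JQ1 arrays. Of 100 splits 2 then gave as many genes, the real one with 101 and another with 5017. That other split had the second largest contrast in control signal (3.33) and many times the real count, a structure of the arrays. The split with the largest contrast, 3.63, gave 0 genes. With the covariate the real split gave 686 genes and the highest other 0. In both, the share of 2 in 100 was under 0.05, which bounds chance and does not exclude it, since another split gave more genes than the real one. In the other splits the effect of JQ1 can enter the spread within groups, which lowers their counts. For the difference this holds only for what remained of the effect after its average was taken out. The splits also exchanged arrays across numbered pairs, and those that part all pairs were not counted separately for these comparisons. In Kelly 1 of 10 splits, the real one, gave 1178 genes, and the highest other gave 0, including the 3 others that part all 3 numbered pairs; in BE(2)-C 1 of 10 gave 850 and the highest other 0; between the lines 1 of 10 gave 2735 and the highest other 0. Splits of 3 against 3 are too few for a share under 0.05.

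Probe sets with no gene name were outside the comparisons. Of 2473, 49 passed in Kelly (7 higher and 42 lower), 65 in BE(2)-C, 128 in the average and 7 in the difference.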

How the results depend on the processing

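Settings planned beforehand were the probe set rule, level filter, normalization, prior, replicate block, arrays left out and list tests; the control-signal settings, and several uses of planned settings on other results, were chosen after the data were seen. A named gene or list counts as reversed only where it was called in either fit. Over named genes, 6579 alternative values kept direction and side of the threshold, 558 fell short of it, 69 newly passed and 2 reversed; over lists these were 2690, 234, 76 and 0. TNFRSF10B, which has disagreeing probe sets, went to 0.31 in Kelly and 0.15 in the average without _x_at probe sets (limma adjusted p = 0.465 and 0.677). The cause of the changes below was not tested except where fewer genes or arrays entered the fit. Signal over background was not estimated, and its effect on dim genes was not tested.

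With the control signal as a covariate the counts were 2293 in Kelly, 2751 in BE(2)-C, 3683 in the average, 686 in the difference (407 at 2-fold) and 4798 between lines, with 470 genes higher and 562 lower in both lines. With the replicate block and this covariate they were 2317, 2723, 3578 and 715 (486 at 2-fold), with 391 and 571 shared. Without the 3 arrays of highest control signal they were 4502 (1105 at 2-fold), 2565, 5815 and 457 (363 at 2-fold), with 519 and 910 shared and r = 0.595. The mean control signal was still higher with JQ1 in both lines in that setting. The mean of all probe sets gave 411, 274 and 246 genes at 2-fold in Kelly, BE(2)-C and the average; only genes above the median level gave 52 in the difference (52 at 2-fold) and r = 0.486; quantile normalization gave 210 genes higher in both; the 6 Kelly arrays alone gave 584.

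MYCN reached -0.43 in Kelly and -0.67 in BE(2)-C with the mean of its probe sets (limma adjusted p = 0.0333 and 0.00386), and passed with the trend and robust prior at -0.34 and -0.33 (adjusted p = 0.0279 and 0.0471). Its dimmer probe sets gave -0.99 and -1.03 in BE(2)-C. Its average call was lost at -0.34 with the replicate block (adjusted p = 0.0762) and at -0.19 in another probe set. Its adjusted p in the average spanned 0.0266 to 0.0899 when 1 array was left out and 0.000564 to 0.487 over all alternatives.

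With the estimated correlation 0, 1, 0, 0 and 0 lists passed in Kelly, BE(2)-C, the average, the difference and between lines, and 0 in each with the covariate as well. With fry 5 passed in Kelly, 3 of them among the 8 that camera called, and 0 in the difference, and above the median level 5 passed in Kelly and 1 between lines.

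Leaving out 1 array gave 603 to 2167 genes in Kelly (482 to 1192 at 2-fold), 322 to 1210 in BE(2)-C (265 to 464), 1359 to 2461 in the average (423 to 556), 39 to 212 in the difference (39 to 210) and 1956 to 3163 between lines (1408 to 1688). MYCN spanned -0.37 to -0.31 in Kelly, -0.37 to -0.29 in BE(2)-C and -0.36 to -0.32 in the average. List calls spanned 7 to 12, 10 to 12, 9 to 12, 6 to 9 and 3 to 6. Genes higher in both spanned 52 to 163, lower in both 100 to 268, and r 0.191 to 0.578. Arrays that moved a count by over 1.5 times are named beside that count.

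The replicate block gave 1523 genes in Kelly, 793 in BE(2)-C, 2107 in the average and 100 in the difference, of which 1068, 660, 1786 and 73 also passed without it. In BE(2)-C same-numbered samples had residual correlations of -0.07, 0.53 and -0.74, and of 0.21, -0.27 and -0.28 with the control signal in the model. The numbers did not meet the pairing rule used here, and the labels leave open whether they mark a shared culture or day. Over all comparisons the block ended the MYCN call of the average, 16 other named-gene calls and 3 list calls, and added 4 and 3. It could not be fitted between the lines, and was not run there.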

Other observations

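The families in the first paragraph were chosen after values were seen. Of 27 measured HOX genes 4 fell in Kelly, all in the HOXC cluster: HOXC8 (-3.46), HOXC9 (-1.44), HOXC4 (-0.79) and HOXC6 (-0.62). In BE(2)-C 2 fell, HOXC8 (-2.16) and HOXC4 (-1.10). HOXC5, HOXC10, HOXC11, HOXC12 and HOXC13 did not pass in either line, the median over the family was 0.21 in Kelly and -0.09 in BE(2)-C, and the family had limma camera adjusted p = 0.337 in Kelly and 0.0392 in BE(2)-C (adjusted p = 0.674 and 0.745 with an estimated correlation). With quantile normalization HOXC4 and HOXC6 did not pass in Kelly, and with the control signal as a covariate HOXD8 fell there as well and HOXC11 in BE(2)-C; median centring called the same genes. Of 50 histone genes outside the fixed list 11 rose and 0 fell in the average (limma camera adjusted p = 4.77e-09 over 4 families; adjusted p = 0.433 with an estimated correlation), and 10, 10 and 13 rose and 0 fell with quantile normalization, median centring and the covariate. Their median was 0.55 in Kelly and 0.08 in BE(2)-C. The median difference between the lines, -0.34, was opposite to the more positive change of the fixed histone list in BE(2)-C (camera adjusted p = 0.000266; adjusted p = 0.36 with an estimated correlation), and it was -0.35, -0.29 and -0.27 in these settings. Of 48 small nucleolar and Cajal body RNAs 4 rose and 1 fell in the average, and with quantile normalization 6 rose and 0 fell; SCARNA20 rose in both lines under each of these settings. Among 16 tubulins TUBB3 and TUBG2 rose and TUBA1C fell in the average under each of these settings. The median difference between the lines was also negative in HOX genes (-0.27), small nucleolar and Cajal body RNAs (-0.31) and tubulins (-0.40). That of the histone genes outside the fixed list was therefore not particular to them.

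Genes that set a line apart were compared with the rest, as a hypothesis; its first test and that with genes chosen on the JQ1 arrays were set before the values were seen, and the test with genes chosen on 1 DMSO array was added after the first result and before its own. Of 94 genes at least 8-fold higher in Kelly under DMSO, 40 fell and 3 rose with JQ1 in Kelly (median log2 fold change -0.68, in 3 of 3 JQ1 arrays below 0; the middle 95% of 10000 random lists matched on level spanned -0.26 to -0.02). Of 71 genes at least 8-fold higher in BE(2)-C, 21 fell and 1 rose there (median -0.28, 3 of 3 arrays, random lists -0.10 to 0.11). The medians of the Kelly and BE(2)-C genes in the other line were -0.06 and 0.00. By the choice, these genes were at least 8-fold lower in the other line and may have had little room to fall there. Those medians therefore do not show that the falls were particular to a line. Choosing genes on DMSO arrays and measuring falls against the same arrays can produce such a fall. With genes chosen on 1 DMSO array and falls measured against the others, the Kelly medians were -0.67, -0.65 and -0.71, all below their random lists. The BE(2)-C medians were -0.73, -0.30 and 0.000728, the last inside its random range, so chance error of the DMSO arrays stays open for BE(2)-C. Choosing on the JQ1 arrays instead gave medians of -0.06 in Kelly (random lists -0.18 to 0.09) and 0.0996 in BE(2)-C (-0.05 to 0.13). Both lay inside their random ranges, so no fall beyond that of other genes was seen with that choice. Neither of the outcomes set beforehand was met. The test cannot decide the question, since genes that fell drop out of that choice. That JQ1 lowers genes that set a line apart may hold in Kelly as a hypothesis, and for BE(2)-C it stays open.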
